A study of Mus musculus with 6 samples.

How the data were processed

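RNA-seq libraries of primary mouse ventricular cardiomyocytes were compared between 2 groups of 3. The cells came from C57BL/6J mice of 1 day of age. One group carried a short hairpin RNA (shRNA, an RNA that lowers its target transcript) against Gdf11 (shGDF11). The other carried a control hairpin, which the sample labels call sh-nc and the treatment protocol sh-Vector. Per the labels' protocols, the hairpins were delivered at a multiplicity of infection of 200, total RNA was extracted with TRIzol after 48 h, and the libraries were sequenced on an Illumina HiSeq X instrument. Samples were grouped by their treatment label. The labels number the samples 1 to 3 in each group and do not say whether a number marks a culture or a hairpin. Nothing in the labels says that the 3 samples of a group came from separate cultures, so the p-values measure only the spread between these samples, which may be technical.

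The deposited table holds FPKM values (fragments scaled by gene length and by the depth of the library), which the authors computed for 54532 Ensembl genes in the 6 libraries, beside each gene's name, position, length and biotype. The submitters' processing notes name CASAVA 1.8, HISAT2 2.0.5, featureCounts 1.5.0-p3 and the builds GRCm38 and mm10, without a role or an order. The annotation release and whether counting used the strand are not given in the sources used here. Of 54409 gene identifiers also found in a reference annotation of GRCm38, 53499 had the same coordinates there, so coordinates are given on GRCm38. The table listed 27 gene names in the form of dates, and these genes were named through their identifiers.

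In each library, FPKM times gene length was a whole multiple of 1 step: 100% of the positive values lay within 0.05 of a whole read. This gave the reads behind the values. The listed genes held 15267083 to 16152910 reads per library, which was 96.9% to 97.6% of the reads that the scaling by depth implies. The remaining reads are not in the genes listed. At these depths, a count of 3 reads, taken as the floor, corresponds to 0.18 to 0.191 FPKM for a gene of 1 kb. Intervals on reads cover counting error only. Without strand, reads of overlapping genes on opposite strands cannot be told apart. Reads of near-identical copies such as Tubb2a and Tubb2b or Hspa1a and Hspa1b may have been split between them.

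The main tests, gene lists, panel and rule for named genes were chosen before the data were examined. Genes with a mean of at least 0.5 FPKM over the 6 libraries were tested on log2(FPKM + 0.5) with limma 3.58.1 (moderated test, eBayes with a variance trend, two-sided) in R 4.3.3. A gene was called at a Benjamini-Hochberg adjusted p under 0.05. Fold changes are shGDF11 minus control on this scale, which understates the change of low genes. Because the unit was FPKM, no count test was the main test. Limma voom on the recovered reads was an alternative.

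The 29 gene lists, 22 of pathways and 7 of cell type markers, held 665 symbols, of which 3 matched no gene. They were tested with limma's camera at a preset correlation between genes of 0.01, two-sided, with adjustment over the 28 lists that had at least 5 measured genes. Gdf11 was left out of every list. None of the 9 erythroid markers matched in the table passed the filter on low values. Camera with an estimated correlation, camera on ranks and fry, which tests whether the genes of a list move on balance one way, were alternatives. With an estimated correlation the adjusted p rose even where the estimate lay below 0.01, as in the hypertrophy (-0.0291) and HIF-1 (-0.00051) lists. So a call lost under that alternative does not by itself show that the list's genes vary together. Among lists that lost their call, the estimate was also below 0.01 in the ligand, receptor and SMAD list (-0.033). It was above 0.01 in the immediate early (0.178), unfolded protein (0.117), cell cycle (0.115) and NRF2 (0.0697) lists. The SMAD2/3 (0.0369), fibroblast (0.0235) and macrophage (0.0115) lists also lay above it. For these lists the preset may be too low and the main camera adjusted p too small.

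The named genes were Gdf11, the measured genes of a panel of 20 (ligands, receptors, SMAD, VEGF, HIF, natriuretic peptide and myosin genes), and up to 4 members of each list with the smallest p. To these came the 8 largest rises and 8 largest falls among called protein-coding genes with at least 5 FPKM in the higher group and no overlap between the groups' values. List members named beyond that rule, to identify a small count, were chosen after their values were seen.

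Other alternatives were the pseudocount, the filter, the scaling of the libraries, the variance model, library weights, a replicate block and the omission of each library. Removal of trends with GC content and gene length was added after the data were seen. The gene test was tested on simulated reads drawn from the real means and library sizes for the comparison of shGDF11 with control. Over 15550 genes it recovered 69.7% of genes changed by 1.5-fold, 82.8% by 2-fold and 93.4% by 4-fold, with 11 false calls. With no change simulated, 2 of 15555 genes and 0 of 28 lists were called. A simulated 1.5-fold fall of the HIF-1 list was called, with 0 other lists. Genes were drawn independently at the same dispersion (0.00449), without correlation between genes or effects of a library. So the simulation does not give the error rates of the tests on the real libraries.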

Results

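The transcriptome of neonatal mouse ventricular cardiomyocytes was measured in 3 libraries with a hairpin against Gdf11 and 3 with a control hairpin. The series concerns Gdf11 deficiency, cardiac angiogenesis and heart failure under pressure overload, and this comparison asks which cardiomyocyte transcripts differ when Gdf11 is lowered. Each library held 15267083 to 16152910 reads in listed genes, and 24117 to 25324 genes had at least 1 read. Over the genes tested, Spearman's rho across genes was 0.972 to 0.979 between control libraries and 0.982 to 0.983 between shGDF11 libraries. Between the groups it was 0.949 to 0.962. The first principal component held 48.5% of the variance and separated the groups. No library repeated the counts of another in its group, with a chi-square between them of 3.63 to 20.3 per degree of freedom. Genes of ribosomal RNA, nuclear and mitochondrial, took 0.298% to 0.319% of reads in the control libraries and 0.47% to 0.502% in the shGDF11 libraries.

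Gdf11, a secreted ligand of the TGF-beta family, was lower in each of the 3 shGDF11 libraries than in each control library. The gene (ENSMUSG00000025352) lies on the minus strand of chromosome 10 at 128882295 to 128891718 of GRCm38. Its level was 2.46 ± 0.26 FPKM in control and 0.665 ± 0.0986 FPKM in shGDF11 (mean ± SD, n = 3 in each group, as for all levels given here as mean ± SD), or 27.1% of control. The controls held 153 to 176 reads of Gdf11 and the shGDF11 libraries 40 to 51. The log2 fold change was -1.34 ± 0.125 (SE), with a limma adjusted p of 0.00079. An exact two-sided permutation test gave p = 0.1, the smallest that 3 against 3 allows. On recovered reads, without the pseudocount's damping, the limma voom log2 fold change was -1.88.

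Lowering Gdf11 went with changed levels of 4253 of 15418 tested genes by limma (27.6%), of which 2227 were higher and 2026 lower. Counts of called genes in a list are to be read beside that share. The falls included cytokine, hypoxia-response, SMAD2/3 target and immediate early genes and the natriuretic peptide gene Nppb. The rises included interferon-stimulated genes and chaperones of the endoplasmic reticulum. Changes of at least 2-fold were fewer, with 231 genes higher and 162 lower. The values of the groups did not overlap for 4250 of the called genes, which follows largely from the call and is no separate support. The exceptions were the microRNA genes Mir7051, Mir503 and Mir7007, named after their values were seen. Of all tested genes, 45.8% had no overlap, against 10% by chance for 3 against 3. The total was 2722 without shGDF11 replicate 1, 2346 without shGDF11 replicate 2 and 2535 without shGDF11 replicate 3. After rescaling to TPM, 66.3% of the called genes were higher, against 52.4% in the main test.

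Among protein-coding genes of at least 5 FPKM, the largest rise was that of Hist1h2bn, a histone H2B gene, from 0, 3 and 1 reads in the control libraries to 40, 44 and 49. The depth-scaled ratio of its reads was 33.0 (95% exact interval 12.6 to 123, counting error only). Hlf, a PAR bZIP transcription factor, followed, from 1.37 ± 0.194 to 7.23 ± 0.511 FPKM (log2 fold change 2.05). Pirt, a regulator of TRP channels, rose from 2.73 to 12.0 FPKM, and Fndc5, the precursor of irisin, from 2.38 to 10.6 FPKM. Wfdc1 and Sh2d4a rose by 1.87 and 1.84 on the log2 scale, and the aldehyde dehydrogenase gene Aldh1a7 rose from 1.19 to 5.33 FPKM. The beta-tubulin gene Tubb2a rose from 24.4 ± 0.704 to 88.9 ± 2.95 FPKM. Hist1h2bn, Tubb2a and Aldh1a7 have near-identical copies that can share their reads, so their own levels are uncertain.

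The largest fall was that of Csf3, the granulocyte colony-stimulating factor, from 6.80 ± 0.159 to 0.881 ± 0.244 FPKM (log2 fold change -2.42). Nppb, which encodes B-type natriuretic peptide, fell from 84.2 ± 11.2 to 15.7 ± 1.09 FPKM. Wif1, a secreted Wnt inhibitor, fell from 19.0 to 4.34 FPKM. Gipr, the receptor of an incretin hormone, fell from 13.2 to 3.07 FPKM. Egln3, an oxygen-sensing prolyl hydroxylase, fell from 255 ± 12.7 to 68.7 ± 1.57 FPKM. Rnf208 fell by 1.85 and the chemokine gene Cxcl5 by 1.84 on the log2 scale. The inducible chaperone gene Hspa1a fell from 7.36 to 1.48 FPKM and can share reads with its copy Hspa1b. The limma adjusted p of these 16 genes was between 5.4e-05 and 0.00051.

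**Figure D1:**
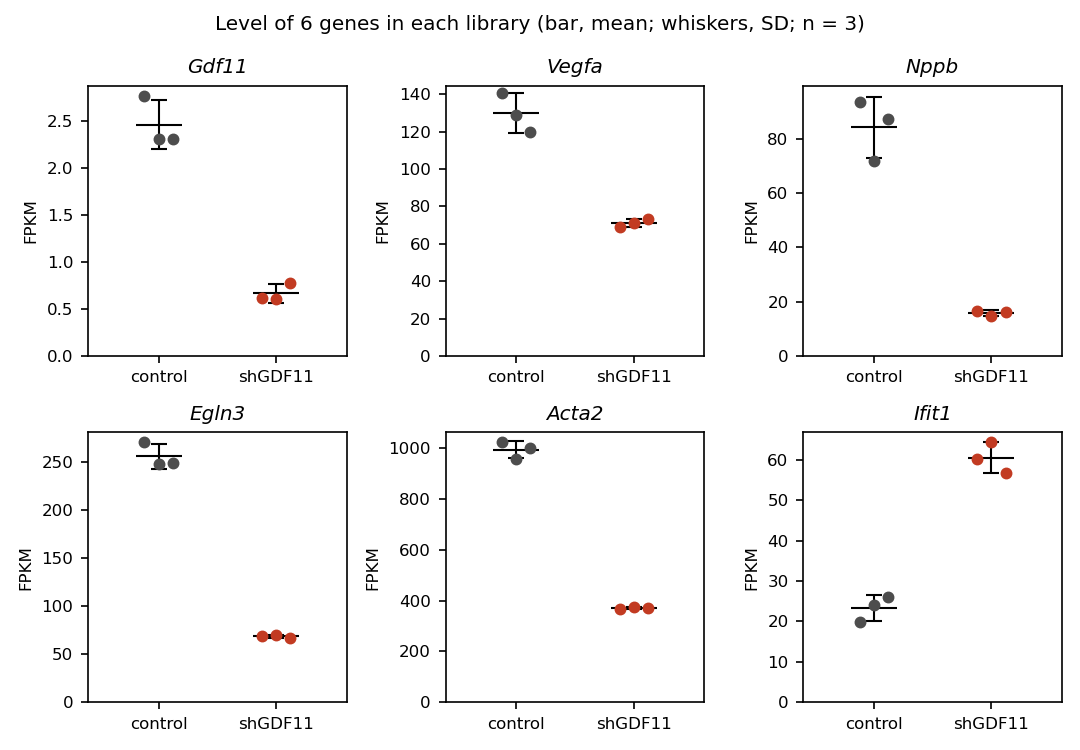
FPKM of Gdf11, Vegfa, Nppb, Egln3, Acta2 and Ifit1 in each library of the control and shGDF11 groups (points, 1 per library; bar, mean; whiskers, SD; n = 3). In the first 5 genes the 3 shGDF11 libraries lie below the 3 controls, and in Ifit1, whose mean rose from 23.3 to 60.5 FPKM, they lie above them.

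Vegfa, the main angiogenic growth factor of the VEGF family, fell from 129.8 ± 10.6 to 71.1 ± 2.04 FPKM (log2 fold change -0.86 ± 0.0725 SE, limma adjusted p = 0.00057). Vegfb rose from 40.6 ± 2.22 to 55.7 ± 0.778 FPKM (limma adjusted p = 0.0023). Vegfc was at 5.60 ± 0.243 and 5.48 ± 0.802 FPKM and was not called (limma adjusted p = 0.83). Of the 30 angiogenic factors, all measured, 13 fell and 7 rose (14 and 11 adjusted over the list alone). Those that fell included Adm (adrenomedullin, 41.9 to 14.3 FPKM), Apln (apelin, 16.7 to 6.15 FPKM) and Cxcl12 (9.46 to 4.91 FPKM). Those that rose included Vegfb and, named after their values were seen, Fgf1 (22.8 to 33.8 FPKM) and Vegfd (8.77 to 14.6 FPKM). As a list the angiogenic factors were not called by camera (adjusted p = 0.21), and over 23 alternatives the adjusted p ran from 0.003 with fry to 0.394. At a mean of at least 5 FPKM camera called the list as lower (adjusted p = 0.0402). There 11 of 18 angiogenic factors fell and 4 rose, with a median log2 fold change of -0.49 against -0.02 in the main test.

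Genes induced by the hypoxia-inducible factor HIF-1 were lower as a list. Of 22 measured, 15 fell and 1 rose (16 and 2 adjusted over the list alone), with a median log2 fold change of -0.52. The falls were led by Egln3 and by Ero1l, an oxidase of the endoplasmic reticulum (53.4 to 21.8 FPKM). Slc2a1, the glucose transporter GLUT1, fell from 83.0 to 36.9 FPKM. Ankrd37 fell from 10.4 to 5.48 FPKM and shares 22.7% of its exon bases with Lrp2bp on the other strand. The 1 that rose was Hk2, a hexokinase, by 0.31 on the log2 scale. Vegfa and Adm belong to both this list and the angiogenic factors. The rise of Hk2 was not called without control replicate 2 or any 1 shGDF11 library, or with the replicate number as a block. By camera the adjusted p of the list was 7.1e-07. It stayed called with an estimated correlation (camera adjusted p = 0.0325, the highest of 23 alternatives, whose lowest was 2.1e-10). The HIF subunit genes themselves were not called: Hif1a was at 83.3 ± 9.45 and 80.9 ± 1.57 FPKM and Epas1 at 9.57 ± 0.667 and 9.96 ± 0.448 FPKM (limma adjusted p = 0.80 and 0.61).

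Target genes of SMAD2 and SMAD3, the transcription factors that GDF11 receptors activate, were lower. The list was called by camera (adjusted p = 3.0e-06), but not with an estimated correlation (adjusted p = 0.0754), the highest of 23 alternatives, whose lowest was 4.4e-08. Of 18 measured, 13 fell and 0 rose (13 and 1 adjusted over the list alone), with a median log2 fold change of -0.51. The smooth muscle actin gene Acta2 fell from 993 ± 34.2 to 370.3 ± 3.57 FPKM. It is also in the smooth muscle list, as Ctgf is in the hypertrophy list and Cyr61 in that of angiogenic factors. Ctgf (Ccn2) fell from 87.7 to 37.7 FPKM, with 23.2% of its exon bases shared with an antisense gene, and Tgfbi fell from 22.9 to 11.4 FPKM. Smad7, the inhibitory SMAD, fell from 9.65 ± 2.34 to 5.19 ± 0.733 FPKM (limma adjusted p = 0.0145). Without shGDF11 replicate 2 its limma adjusted p was 0.0547, with a range over the alternatives up to that value from 0.00093.

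The ligand, receptor and SMAD genes of the pathway were less uniform. Of 22 measured, 5 fell and 2 rose (7 and 2 adjusted over the list alone). Inhba, a subunit of activin A, fell from 13.9 to 7.72 FPKM, Fstl3, an activin and GDF antagonist, from 2.62 to 0.826 FPKM, and Tgfb1 from 17.0 to 10.6 FPKM. The other falls were Tgfb3 and Smurf1, and the rises were the receptors Tgfbr2 and Tgfbr3. Of the panel, Smad2, Smad3, Smad4, Acvr1b, Acvr2a, Acvr2b, Tgfbr1 and Fst were not called, with log2 fold changes between -0.31 and 0.14. Mstn, the closest relative of Gdf11, was below the filter, with 2 to 17 reads per library. Camera called the pathway list (adjusted p = 0.0401), but not with an estimated correlation (adjusted p = 0.16). The camera adjusted p was 0.0682 without control replicate 2 and 0.0526 without shGDF11 replicate 2. It was 0.0536 after rescaling to TPM, 0.0642 over protein-coding genes and 0.216 at a mean of at least 5 FPKM, the highest of 23 alternatives, whose lowest was 0.00013. The 5 falls were 3 without control replicate 2, shGDF11 replicate 2 or shGDF11 replicate 3. The 2 rises were 1 without control replicate 1, control replicate 3 or shGDF11 replicate 3, and 0 without shGDF11 replicate 1 or 2. With the GC and length trends removed, 10 of the pathway genes fell and 2 rose. Of 15 targets of BMP signalling through SMAD1 and SMAD5, Id2 and Hey2 rose and Grem1, Bmper and Id1 fell (2 higher and 3 lower also adjusted over the list alone). That list was not called by camera (adjusted p = 0.24).

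NF-kB and cytokine genes showed the lowest median of all lists in the main test, at -0.83 on the log2 scale. At a mean of at least 5 FPKM their median was -0.64, above that of the immediate early genes (-0.71). Of 23 NF-kB and cytokine genes measured, 17 fell and 1 rose (18 and 2 adjusted over the list alone). Lcn2, an iron-binding acute-phase protein, fell from 49.2 to 17.6 FPKM, Ptgs2, the inducible cyclooxygenase, from 7.39 to 1.89 FPKM, and Cxcl1, a neutrophil chemokine, from 19.1 to 5.51 FPKM. The 1 that rose was the adhesion molecule gene Vcam1 (log2 fold change 0.38). This list had the smallest camera adjusted p (2.2e-09) and stayed called with an estimated correlation (camera adjusted p = 0.0325, the highest of 23 alternatives, whose lowest was 9.5e-13). Immediate early genes, which respond to stimuli within minutes, were also lower, with 12 falls and 0 rises among 20 measured (13 and 0 adjusted over the list alone). The immediate early list was called by camera (adjusted p = 7.1e-07), but not with an estimated correlation (adjusted p = 0.16), the highest of 23 alternatives, whose lowest was 2.1e-10. Ier3 fell from 108.4 ± 15.1 to 33.5 ± 2.45 FPKM, Fosl2 from 13.4 to 5.90 FPKM, and Dusp1, a phosphatase of MAP kinases, by 0.95 on the log2 scale.

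Interferon-stimulated genes moved the other way. Of 32 measured, 19 rose and 0 fell (24 and 0 adjusted over the list alone), with a median log2 fold change of 0.37. Ifit1, an antiviral RNA-binding protein, rose from 23.3 ± 3.20 to 60.5 ± 3.85 FPKM. The transcription factors Stat2 and Irf7 rose from 16.6 to 29.5 and from 14.5 to 26.6 FPKM, and Oasl2 rose from 7.65 to 13.0 FPKM. Camera called the interferon list (adjusted p = 2.9e-08), also with an estimated correlation (adjusted p = 0.0325, the highest of 23 alternatives, whose lowest was 2.0e-12). Without shGDF11 replicate 1 the count of rises was 12.

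Genes associated with hypertrophy were lower as a list, with 7 falls and 2 rises among 16 measured in both counts, over all genes and adjusted over the list alone. The hypertrophy list was called by camera (adjusted p = 0.0047), but not with an estimated correlation (adjusted p = 0.13), the highest of 23 alternatives, whose lowest was 4.8e-05. Besides Nppb and Ctgf, the calcineurin regulator Rcan1 fell from 58.0 ± 4.53 to 19.2 ± 0.585 FPKM and the skeletal actin gene Acta1 from 29.8 to 16.5 FPKM. The rises were Mef2a and Fhl1. The count of rises was 1 without control replicate 1 or 2 or any 1 shGDF11 library. It was also 1 with no filter on low values, after rescaling to TPM, without the variance trend and with the replicate number as a block. Nppa, the atrial natriuretic peptide gene, was at 2022 ± 463 and 1833 ± 119.8 FPKM and was not called (limma adjusted p = 0.61); 61.5% of its exon bases lie opposite an antisense gene. Myh7, the beta myosin heavy chain, fell from 15.5 ± 1.28 to 8.79 ± 1.15 FPKM (limma adjusted p = 0.0026). Myh6, the alpha chain, was at 1605 ± 172 and 1337 ± 102.5 FPKM and was not called (limma adjusted p = 0.11).

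Sarcomere genes moved in both directions, with 8 rises and 7 falls among 27 measured (10 and 8 adjusted over the list alone). Tcap, the titin cap, rose from 23.9 to 63.1 FPKM, Tnni1, the slow skeletal troponin I, from 79.3 to 119.9 FPKM, and Myom2 from 25.1 to 36.7 FPKM, while Acta1 and Myh7 fell. Among 26 calcium handling and ion channel genes, 7 rose and 11 fell (8 and 11 adjusted over the list alone). The potassium channel gene Kcnj5 rose from 18.8 to 28.1 FPKM. Gja1, connexin 43, fell from 238.8 to 159.9 FPKM, and Atp2a2, the calcium pump SERCA2, from 744 to 543 FPKM. Camera called neither list (adjusted p = 0.59 and 0.21). The 8 sarcomere rises were 5 without shGDF11 replicate 2 or 3, and with no filter on low values 5 rose and 5 fell. The 11 falls of channel genes were 7 without control replicate 2 or 3, 5 without shGDF11 replicate 1, and 6 without shGDF11 replicate 2 or 3. After rescaling to TPM 7 channel genes rose and 5 fell, and with no filter on low values 7 rose and 7 fell.

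Genes of the unfolded protein and ATF4 responses were higher. The list was called as higher by camera (adjusted p = 1.7e-05), but not with an estimated correlation (adjusted p = 0.16), the highest of 23 alternatives, whose lowest was 8.8e-08. Of 28 measured, 17 rose and 4 fell (18 and 4 adjusted over the list alone), with a median log2 fold change of 0.53. Hspa5, the chaperone BiP, rose from 166.4 to 273.8 FPKM, and Pdia4, a disulfide isomerase, from 37.2 to 86.3 FPKM. The transcription factor gene Ddit3 (CHOP) rose from 13.1 to 28.7 FPKM and Mthfd2, a mitochondrial folate enzyme, from 18.7 to 34.8 FPKM. The 4 falls were the stress-response genes Atf3, Sesn2, Slc7a11 and Ppp1r15a, of which Atf3 is also in the immediate early list. The falls were 1 without shGDF11 replicate 2 and 2 without control replicate 3, shGDF11 replicate 1 or shGDF11 replicate 3, as after rescaling to TPM and with no filter on low values.

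NRF2 targets were lower by camera (adjusted p = 0.0217), with 9 falls and 3 rises among 19 measured (10 and 3 adjusted over the list alone). The call was lost with an estimated correlation (adjusted p = 0.29, the highest of 23 alternatives, whose lowest was 0.0029) and at a mean of at least 5 FPKM (camera adjusted p = 0.0799). Gstm1, a glutathione transferase, fell from 112.3 to 75.2 FPKM and the quinone reductase gene Nqo1 from 24.9 to 17.5 FPKM. The rises were G6pdx, Ftl1 and Txnrd1. The 9 falls were 5 without control replicate 3 or any 1 shGDF11 library, after rescaling to TPM and with no filter on low values. Cell cycle genes were higher by camera (adjusted p = 0.0085), with 15 rises and 3 falls among 34 measured (17 and 3 adjusted over the list alone). The list's camera adjusted p with an estimated correlation was 0.34, the highest of 23 alternatives, whose lowest was 0.00069. The mitotic kinase gene Aurka rose from 10.6 to 19.1 FPKM, Ube2c from 21.5 to 34.5 FPKM and the kinesin gene Kif11 from 6.66 to 11.5 FPKM. The falls were Ccne1 (cyclin E1, 16.4 to 10.6 FPKM), Rrm2 and Mcm3. Without shGDF11 replicate 2 the count of cell cycle rises was 9.

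Metabolic and structural lists were not called by camera. Among 32 oxidative phosphorylation genes 3 rose and 9 fell (4 and 12 adjusted over the list alone; camera adjusted p = 0.18), and Cox6a2, a heart and muscle subunit of cytochrome oxidase, rose from 130.6 to 273.3 FPKM. The other rises were Ndufb8 and Atp5h, and without control replicate 3 the rises were 5. The 9 falls were 0 without shGDF11 replicate 2 or 3, 5 without shGDF11 replicate 1 and 4 without control replicate 3, and without control replicate 2 the list was called as lower (camera adjusted p = 0.0429, the lowest of 23 alternatives, whose highest was 0.747). After rescaling to TPM 3 of these genes rose and 2 fell, with no filter on low values 3 and 1, and without the variance trend 3 and 4. With library weights 7 rose and 11 fell, on recovered reads 5 and 12, and over protein-coding genes 5 and 9. Among 24 fatty acid oxidation genes 4 rose and 5 fell (6 and 6 adjusted over the list alone; camera adjusted p = 0.64). Acaa2 rose from 129.5 to 175.1 FPKM, and Acadvl fell from 39.3 to 21.5 FPKM, with 42.9% of its exon bases shared with Dvl2 on the other strand. These 5 falls were 3 without control replicate 3 or any 1 shGDF11 library and 8 without control replicate 1. They were 3 after rescaling to TPM and with no filter on low values, and 8 with the GC and length trends removed. Among 18 glycolysis genes 2 rose and 5 fell (4 and 7 adjusted over the list alone, camera adjusted p = 0.20). The estimated correlation of this list was 0.59, far above the preset 0.01, and reads of its member Gapdh varied widely within each group. Aldoc rose from 4.47 to 9.04 FPKM, and the lactate transporter gene Slc16a3 fell from 51.1 to 20.3 FPKM. The 2 glycolysis rises, Aldoc and Ldhb, were 5 without control replicate 1. They were 4 after quantile normalization or rescaling to TPM, over protein-coding genes, with library weights, on recovered reads and with the GC and length trends removed. With no filter on low values 1 glycolysis gene rose and 3 fell. Among 30 extracellular matrix genes 7 rose and 6 fell in both counts, over all genes and adjusted over the list alone (camera adjusted p = 0.79; median log2 fold change 0.05, mean -0.01, with the direction of the test up). Lox, lysyl oxidase, fell from 45.7 to 25.8 FPKM, and Col3a1, named after its value was seen, rose from 43.9 to 58.0 FPKM. The matrix rises were 4 without shGDF11 replicate 2 or 3, and the falls 2 and 3 without shGDF11 replicates 1 and 2. After rescaling to TPM 8 matrix genes rose and 3 fell, and with the GC and length trends removed 11 rose and 6 fell.

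Among 23 p53 and apoptosis genes 5 rose and 7 fell (7 and 7 adjusted over the list alone; camera adjusted p = 0.59). Ccng1, cyclin G1, rose from 166.1 to 392 FPKM, while Cdkn1a, the p21 inhibitor of cyclin-dependent kinases, fell from 139.3 to 84.0 FPKM. The rises were 3 without control replicate 2 or shGDF11 replicate 3 and 2 without shGDF11 replicate 2, where the falls were 4. Among 26 genes of PI3K, AKT and mTOR signalling 4 rose and 4 fell in both counts, over all genes and adjusted over the list alone (camera adjusted p = 0.75). Rises and falls together lie near the share of 27.6% called over all tested genes. Irs1 fell from 2.97 to 1.54 FPKM and Deptor rose from 0.542 to 1.36 FPKM. The rises of this list were 1 without control replicate 2 or any 1 shGDF11 library, and the falls 2 without control replicate 2 or shGDF11 replicate 2. With no filter on low values 1 rose and 4 fell, without the variance trend 2 and 4, after rescaling to TPM 4 and 2, and with library weights 5 and 7. Among 20 cholesterol synthesis genes 3 rose and 7 fell in both counts, over all genes and adjusted over the list alone (camera adjusted p = 0.21). The list was called as lower only by fry (adjusted p = 0.0024, the lowest of 23 limma-based alternatives, whose highest was 0.393). Nsdhl, a sterol dehydrogenase, rose from 8.61 to 14.7 FPKM. The 7 falls were 4 without control replicate 2 or any 1 shGDF11 library. After rescaling to TPM 3 cholesterol genes rose and 3 fell. Among 32 ribosomal protein genes 5 rose and 0 fell in both counts, over all genes and adjusted over the list alone, with log2 fold changes of at most 0.33 in Rpl32 (camera adjusted p = 0.25). These rises were 0 without control replicate 2 or shGDF11 replicate 2 or 3 and 1 without shGDF11 replicate 1 or with no filter on low values. Without control replicate 1 the ribosomal list was called as higher (camera adjusted p = 0.0489, within a range of 0.0279 to 0.77 over 23 alternatives). It was also called after rescaling to TPM and with library weights (camera adjusted p = 0.0279 and 0.0434).

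Markers of other cell types in the cultures also differed between the groups. Of 20 endothelial markers, 13 fell and 0 rose (14 and 0 adjusted over the list alone), with a median log2 fold change of -0.46. Cdh5, VE-cadherin, fell by 0.74 on the log2 scale, Tie1 from 9.39 to 5.42 FPKM, Esam from 7.91 to 4.24 FPKM and Vwf from 2.47 to 1.25 FPKM. Tek, at 4.31 and 4.47 FPKM, and Aqp1, at 5.42 and 5.33 FPKM, named after their values were seen, were not called. Camera called the endothelial list (adjusted p = 9.2e-07), also with an estimated correlation (adjusted p = 0.0325, the highest of 23 alternatives, whose lowest was 2.9e-10). Of 14 macrophage and leukocyte markers, 5 fell and 0 rose (8 and 0 adjusted over the list alone). The macrophage list was called by camera (adjusted p = 0.0045), but not with an estimated correlation (adjusted p = 0.13), the highest of 23 alternatives, whose lowest was 0.00055. The falls were those of C1qb, from 11.7 to 6.46 FPKM, Lyz2, from 114.3 to 85.3 FPKM, Laptm5, C1qa and Mrc1.

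Fibroblast markers were higher by camera (adjusted p = 0.0113). The call was lost with an estimated correlation (adjusted p = 0.16), the highest of 23 alternatives, whose lowest was 0.00017. Of 14 measured, 5 rose and 0 fell (6 and 0 adjusted over the list alone): Dpt from 7.71 to 14.5 FPKM, Islr from 3.63 to 6.49 FPKM, Ly6a, Col14a1 and Ddr2. Of 13 epicardial markers, Sema3d, Tbx18, Aldh1a2 and Upk3b rose and Krt8 and Krt19 fell (5 and 2 adjusted over the list alone; camera adjusted p = 0.10), with 1 fall without shGDF11 replicate 1 or 3. The epicardial list was called as higher by fry and, by camera, with the GC and length trends removed (adjusted p = 4.8e-05 and 0.0461, over 22 alternatives up to 0.25). Of 14 smooth muscle and pericyte markers 4 fell and 0 rose (4 and 1 adjusted over the list alone; camera adjusted p = 0.18), among them Acta2 and Cnn1, the latter from 27.4 to 10.6 FPKM. Fry called the smooth muscle list as lower (limma fry adjusted p = 0.0114, the lowest of 23 alternatives, whose highest was 0.579). The other falls were Cspg4 and Myh11, and without control replicate 2 or shGDF11 replicate 1 the falls were 2. Of these markers 2 rose without control replicate 1 or with library weights, and 3 with the GC and length trends removed. Of 7 Schwann cell and neuron markers, S100b and Prph rose and Erbb3 fell (3 and 1 adjusted over the list alone, camera adjusted p = 0.48). Erbb3 was not called without control replicate 1 or 2 or any 1 shGDF11 library. Its call was also lost after rescaling to TPM, with no filter on low values and with the replicate number as a block. With the GC and length trends removed 4 of these markers rose.

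**Figure D2:**
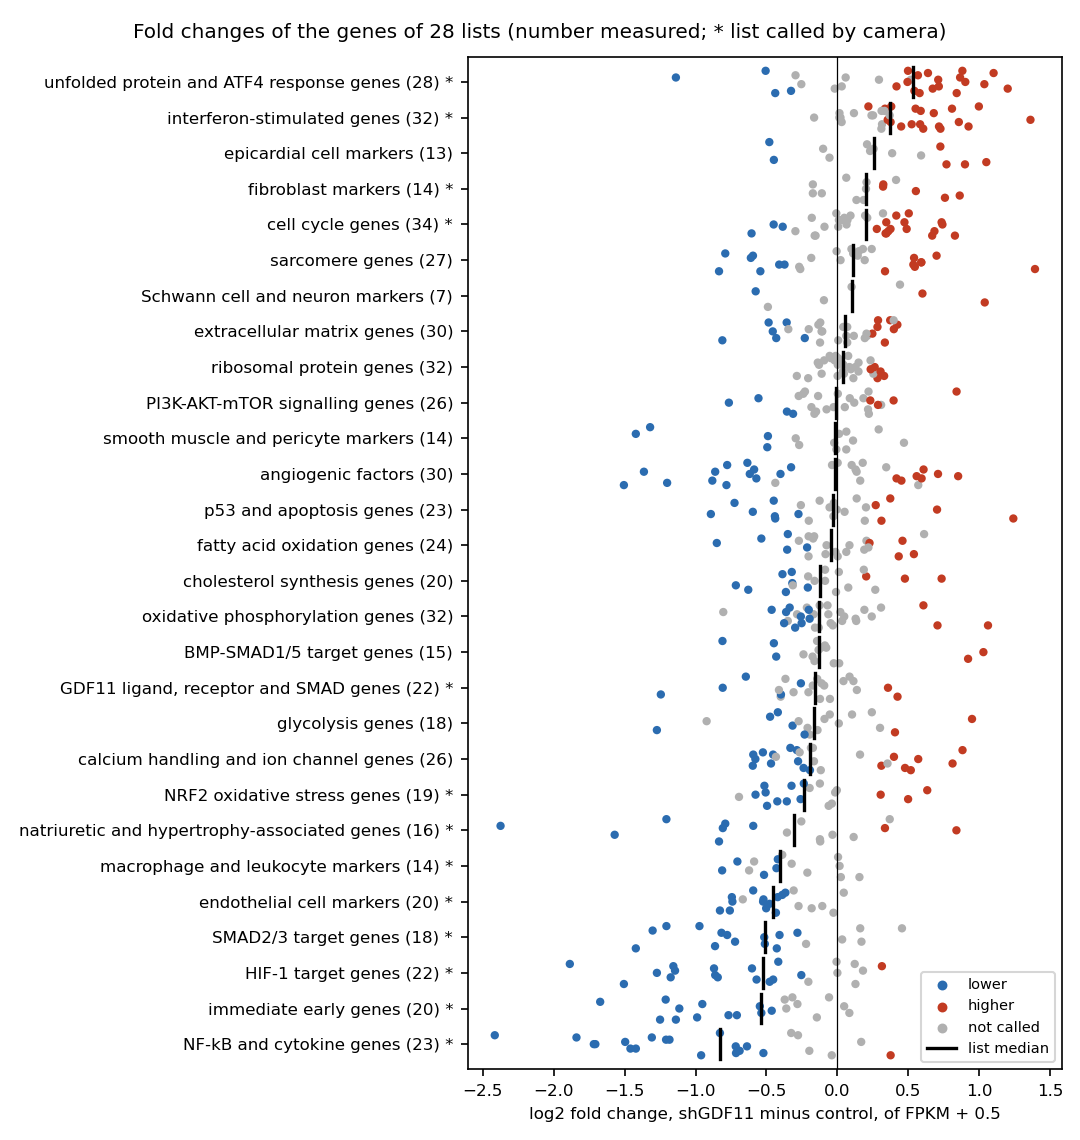
Log2 fold change (shGDF11 minus control, of FPKM + 0.5) of each measured gene of the 28 gene lists (points; blue, called lower; red, called higher; grey, not called), with the median of each list as a black bar and lists ordered by it. The medians run from -0.83 in the NF-kB and cytokine genes to 0.53 in the unfolded protein and ATF4 response genes.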

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

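The GC and length alternative was the only one chosen after the data were seen. Of 128 values of the summary results under 25 alternatives, 113 stayed within 1.5 times the main count or on the same side of the threshold, and 0 reversed. Of 2735 values of 138 other named genes, 2668 kept their side of the threshold, 55 lost it, 12 gained it and 0 reversed. No called gene changed sign under any alternative except 1 with the GC and length trends removed. Gdf11 stayed called, with log2 fold changes from -1.88 to -1.05 and limma adjusted p from 1.7e-05 to 0.0073. It has no value at a mean of at least 5 FPKM, which it did not reach. The panel gave 5 to 8 called genes.

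A minimum mean of 5 FPKM left 7798 genes to test, of which 1474 were higher. At that filter 8 of 13 NF-kB and cytokine genes, 7 of 10 endothelial markers and 2 of 16 PI3K pathway genes were lower, and 1 of 4 epicardial markers was higher. Rescaling to TPM, under which 19679 genes passed the filter, gave 1242 lower genes. The median log2 fold change was then 0.094, against 0.0063 in the main test. The sum of FPKM, by which TPM divides, was 351657 in control replicate 1, 40996 of it from the microRNA gene Gm23935. It was 316233 and 315542 in the other controls and 304770 to 309981 in the shGDF11 libraries. Dividing by these sums raises shGDF11 values against control, so this shift comes with the scaling. A fold change of at least 2 left 393 genes by construction, 231 higher and 162 lower. With 1 library left out, and so fewer samples, the totals were 3064 to 4238 without a control library. Without an shGDF11 library they were 2346 to 2722. Over all these omissions 1263 to 2252 genes were higher and 1083 to 1986 lower. Each omission leaves equally many libraries, so their number does not account for the gap between the 2 groups. Of the main calls, 53.9% were shared without shGDF11 replicate 2 and 85.3% without control replicate 1. With an estimated correlation, 4 lists were called in place of 13: HIF-1 targets, NF-kB and cytokine genes, interferon-stimulated genes and endothelial markers. Fry called 17.

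With the replicate number as a block, 3223 genes were called, 1655 higher and 1568 lower, with 13 lists and 6 panel genes. Among list counts, falls were 4 in oxidative phosphorylation, 3 in fatty acid oxidation, 2 in unfolded protein, 5 in NRF2 and 4 in cholesterol genes. Rises were 2 in PI3K, 3 in p53, 1 in ligand, receptor and SMAD genes, 1 in hypertrophy genes and 0 in ribosomal and in HIF-1 genes. Schwann cell and neuron markers had 0 falls. Gdf11 kept a log2 fold change of -1.34. Libraries with the same number correlated at 0.0153, 0.015 and -0.0521 in their deviations from the group means, and 2 of 6 libraries correlated best with their own number. The samples share only a number. Depth limits genes near the filter, such as Mstn.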

Other observations

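Genes in this paragraph were chosen after their values were seen, and their p-values are limma adjusted. The 2 beta-tubulin genes Tubb2a and Tubb2b rose together, Tubb2b from 19.4 ± 0.791 to 66.0 ± 2.05 FPKM (adjusted p = 5.4e-05). Other tubulin genes did not follow them: Tubb4b fell from 156.5 ± 16.4 to 103.2 ± 6.69 FPKM and Tubb6 from 88.3 to 64.3 FPKM, while Tubb5 (235.8 and 217.3 FPKM) and Tubb3 (36.3 and 38.9 FPKM) were not called. Of the alpha-tubulin genes, Tuba1a (log2 fold change -0.37) and Tuba1c (-0.33) fell, and Tuba1b (-0.30) was not called. Among heat shock genes, Hspa1b fell from 14.8 ± 2.15 to 4.38 ± 0.42 FPKM along with its copy Hspa1a, and the co-chaperone gene Dnajb1 fell from 25.1 to 18.1 FPKM. Hspb1 and Bag3 fell by 0.43 and 0.37 on the log2 scale. Dnaja1 rose from 20.9 to 31.5 FPKM, and Hsp90aa1 (265.6 and 252.5 FPKM) and Hspa8 (375.9 and 430.7 FPKM) were not called. Of the PAR bZIP relatives of Hlf, Tef was at 12.9 and 12.6 FPKM and Dbp at 3.62 ± 0.881 and 4.81 ± 0.341 FPKM. Neither was called, but Dbp was higher in all 19 alternatives and called in 6 of them. Among genes of the circadian clock, Clock rose from 4.06 to 5.94 FPKM and Npas2 from 1.52 to 2.68 FPKM, Nfil3 fell from 21.3 to 14.8 FPKM, and Arntl was at 2.25 and 2.12 FPKM. Cry1 and Cry2, repressors of the clock, fell by 0.47 and 0.51 on the log2 scale. Without shGDF11 replicate 2 the calls of Tuba1a, Tuba1c, Hspb1, Bag3, Cry1 and Cry2 were lost. Other omissions ended the calls of Hspb1 (control replicate 1 or 2, shGDF11 replicate 1 or 3), Bag3 (control replicate 2, shGDF11 replicate 1 or 3) and Tuba1a (control replicate 1 or 2, shGDF11 replicate 3). They also ended those of Tuba1c and Cry1 (shGDF11 replicate 3) and Cry2 (control replicate 2, shGDF11 replicate 1). The adhesion molecules of activated endothelium Selp and Sele fell from 3.83 to 1.22 and from 5.45 to 2.10 FPKM. Hilpda, a hypoxia-induced lipid droplet gene outside the lists, fell from 22.4 ± 2.81 to 6.43 ± 0.672 FPKM. Rescaling to TPM ended the calls of Tuba1a and Tuba1c, the lack of a filter on low values those of Tuba1a, Hspb1 and Cry2, and the lack of a variance trend that of Hspb1. Signs of the called genes named here were kept under all 6 scaling or correction alternatives.

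The tests below on the 3 falling lists and on the endothelial markers, and the count of genes over splits, were chosen after the results were seen. The comparison of long non-coding with protein-coding genes was not among the planned tests either. Its p-value describes a pattern found in these same data. The 6 libraries can be split into 3 and 3 in 10 ways, too few for a share under 0.05. The real split called 4253 genes by limma, and the highest of the other splits called 1, so 1 of 10 splits gave as many. The real split called 13 lists by camera, and the highest of the others called 10, so again 1 of 10 gave as many. Each other split mixes libraries of both groups, so it keeps part of the real difference and adds the rest to the spread within groups. The counts of the other splits therefore do not measure what chance alone gives.

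The HIF-1, NF-kB and immediate early lists were lower together, with a median log2 fold change of -0.69 over their 65 measured members, although the call of the immediate early list was lost with an estimated correlation (camera adjusted p = 0.16, the highest of 23 alternatives, whose lowest was 2.1e-10). With the GC and length trends removed the median was -0.60, which argues against those trends as the whole cause. A loss of endothelial cells and macrophages stays open: the members' median lay 0.317 below that of the 34 markers on recovered reads (difference -0.317), but markers that fall unequally do not bound such a loss, and the lists were picked for their fall. On recovered reads the medians were -1.23 for NF-kB, -0.68 for immediate early and -0.57 for HIF-1 genes, against -0.51 for endothelial and -0.43 for macrophage markers. Lowered Gdf11 and effects of the hairpin on other transcripts also stay open and were not tested apart.

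The endothelial markers fell to different degrees. Fewer endothelial cells with no other change would lower all of these markers alike, but their log2 fold changes on recovered reads differed beyond their errors, which argues against an equal fall of all of them (chi-square of 108.2 over 19 degrees of freedom, p = 1.7e-14). Fewer non-myocytes of every kind would lower fibroblast markers too, and their median log2 fold change was 0.204. A change in endothelial expression, alone or with a smaller number of cells, may account for the fall and was not tested. Fewer endothelial cells stay open as well, since expression of some markers in other cells would blunt their fall.

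Called long non-coding genes were mostly higher in shGDF11, 141 against 32, or 81.5% against 51.0% of called protein-coding genes (Fisher's exact p = 3.4e-16 across genes). Fisher's test here treats genes of the same 6 libraries as independent, so its p-values do not measure the spread between libraries. The share was 73.3% to 86.5% over the 19 alternatives that tested such genes. Reads from coding genes within 5 kb would give no excess where there are none, but 85.7% of those with no coding gene within 5 kb were higher (54 against 9, Fisher's exact p = 1.3e-08). Reads from coding genes further away were not tested and stay open. Genomic DNA or other untargeted material would raise silent genes alike: olfactory and vomeronasal receptor genes held 1848 reads in shGDF11 and 1143 in control, a depth-scaled ratio of 1.61 (95% exact interval 1.49 to 1.73). That ratio lies below the median fold of 2.13 of the 141 higher long non-coding genes, of which 96 had a fold above 1.73. These genes were picked for their rise, so the comparison of folds decides nothing. The receptor genes rose by 0.0028 FPKM on average, against a median of 1.23 FPKM and a smallest rise of 0.441 FPKM, sizes partly set by the call. An even addition of 0.0028 FPKM is too small to account for the rise of any of these genes. Whether the added reads were spread evenly was not tested. RNA spread unevenly, such as unspliced transcripts, and an effect of lowered Gdf11 were not tested and stay open.

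These 3 further findings are given without an explanation. The mitochondrial 16S ribosomal RNA gene mt-Rnr2 was at 849 ± 168 FPKM in control and 1651 ± 128.4 FPKM in shGDF11, while mt-Cytb was at 6010.5 ± 642 and 4215 ± 124.2 FPKM. The fall of mt-Cytb was called in 14 of 20 alternatives. It was not called without any 1 shGDF11 library, after quantile normalization or rescaling to TPM, or with no filter on low values. Gm23935, a microRNA gene, was listed at 40996 FPKM in control replicate 1 and at 1065 to 9686 FPKM in the other libraries; without that library 4238 genes were called. Gapdh held 5391, 1401 and 1054 reads in the controls and 463, 356 and 6499 in the shGDF11 libraries.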
